A study of Mus musculus with 15 samples.

How the data were processed

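Polyadenylated RNA was sequenced from 15 samples of tumour nests collected by laser capture from frozen mouse skin. The mice carried a tamoxifen-inducible Cre recombinase under the keratin 14 promoter, floxed Ptch1 and Trp53 alleles and an Lgr5 allele tagged with GFP. Per the labels, 5 libraries came from nests of mice given vismodegib, an inhibitor of Smoothened, for 28 days, 5 from untreated nests positive for Ki67 and 5 from untreated nests negative for Ki67. The labels give no replicate numbers, so libraries were numbered 1 to 5 within a group in accession order and the numbers pair nothing. They tie no library to an animal. Nests of a group may therefore share animals, in which case the p-values below are too small, and the spread between libraries may be partly technical. The Ki67-negative libraries carry a later range of accession numbers than the other 10, and no sequencing run or date is given in the sources used here. A separate batch for these libraries, if there was one, cannot be separated from the group in either comparison that uses them.

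Reads were aligned with GSNAP to the mouse genome build GRCm38, per the submitters' processing notes. The counts are numbers of reads aligned uniquely to each gene model, per the file headers. The aligner's version, the annotation release and the use of strand are not given in the sources used here. Genes with near-identical copies lose reads to the uniqueness rule, and overlapping or antisense genes cannot be told apart without strand. Each file also holds RPKM values divided by a size factor per library, per the file headers, and these deposited RPKM values were used only to check that each is its count times a constant per gene and per library. Counts were taken as deposited. Of the 36528 NCBI gene identifiers listed, 31049 (85.0%) matched a symbol, and the 5479 others held between 2.258% and 3.934% of a library's counts and stayed in the fit unnamed. No total or blank entry was present. Gene symbols and coordinates come from the RefSeq annotation of the assembly GRCm38.p6, counted from 1. No pair of libraries of a group was identical, and their counts differed by 14.33 to 46.8 times the sampling noise (chi-square per degree of freedom), so none was treated as a duplicate.

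Depth was 4887381 to 10328822 counts per library. Intervals on count ratios are 95% intervals for counting error only. The common biological coefficient of variation was 0.348. Libraries were scaled by TMM, whose factors lay between 0.937 and 1.05, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 17282 genes. Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion in R 4.3.3, over all 15 libraries in 1 fit with 12 residual degrees of freedom and no covariate. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are counts scaled by the TMM-adjusted library size and are given as mean ± SD over the 5 libraries of a group. A count of separated genes is one of genes for which all 5 libraries of 1 group lie above all 5 of the other.

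The labels set up 3 comparisons: vismodegib against untreated Ki67-positive nests, vismodegib against untreated Ki67-negative nests, and untreated Ki67-negative against Ki67-positive nests. The comparisons with vismodegib share its 5 libraries, so their overlap was set beside 20 simulations in which no group changed, beside the overlap of independent lists, and beside 20 splits of the vismodegib libraries into a pair and a trio. Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the first set of alternatives below. Of their 600 entries, 594 matched a listed gene. The 37 lists cover signalling pathways, compartments of the skin and hair follicle and other cell types, and 35 had at least 2 measured members. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated per list and fry were alternatives. A count "adjusted over the list alone" uses the members of that list as the only tests. Of the adipocyte list 1 member was measured and of the B cell and plasma cell list 0, so neither was tested.

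Genes named in the text are the 10 with the largest rise and the 10 with the largest fall in a comparison that were called, had an average log2 CPM of at least 3 and were separated between the groups, leaving out predicted genes and pseudogenes. Ptch1, Trp53, Lgr5, Mki67, Smo and Gli1 were added in every comparison, and up to 4 members with the smallest adjusted p from each list that was called or had a called member. Not all genes that the rule names are printed, and a member of the Hedgehog target list is not reported here. Those named most carry the NCBI gene identifiers and GRCm38.p6 positions 19206 and chromosome 13, 63508328 to 63573460 (Ptch1), 14632 and chromosome 10, 127329882 to 127341579 (Gli1), 15245 and chromosome 8, 79965850 to 80058060 (Hhip), 406220 and chromosome 15, 101858731 to 101869706 (Krt77), 14160 and chromosome 10, 115450314 to 115587780 (Lgr5), 17345 and chromosome 7, 135689784 to 135716450 (Mki67), and 16551 and chromosome 19, 37376382 to 37421863 (Kif11). Ratios of genes with 1 to 3 counts in a group are given with counting intervals in place of fitted fold changes.

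The test was run on simulated counts drawn from the means, dispersions and library sizes of the real libraries, with 200 genes changed by known factors. The changed genes were drawn from those above a minimum mean count and outside every list, and the cell cycle list was also lowered 2-fold. Genes were drawn independently. The shares below thus cover better-expressed genes, and the rate for unchanged genes leaves out correlation between genes. For vismodegib against Ki67-positive nests, edgeR called 47.5% of the 99 genes changed 2-fold and 90.8% of the 98 changed 4-fold among 16963 genes, and 0.06% of the unchanged genes. For vismodegib against Ki67-negative nests it called 41.4% and 88.8% among 16963 genes, with 0.05% of the unchanged genes. For Ki67-negative against Ki67-positive nests it called 42.9% and 76.5% of 98 genes each among 16965 genes, with 0.02% of the unchanged genes.

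The first set of alternatives comprised size factors of the RLE method, no filter on low counts, a stricter filter of 10 counts in 10 libraries, a fit on only the groups compared, the mean log2 CPM of the fibroblast list as a covariate, DESeq2 1.42.0, limma with voomWithQualityWeights, and leaving out each library in turn. A further set was chosen after the data had been seen: a covariate for libraries with more Xist than Ddx3y counts, a covariate equal to the mean log2 CPM of the dendritic and Langerhans cell list, and removal of the trend on gene length, for which 87.4% of the tested genes had a length. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.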

Results

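Gene expression was measured in nests of basal cell carcinoma from mice in which Cre recombinase deletes Ptch1 and Trp53 in keratin 14-expressing epithelium. Ptch1 encodes the receptor that holds the Hedgehog transducer Smoothened inactive, and Trp53 encodes the tumour suppressor p53. The 15 libraries fall into 3 groups of 5: nests left after 28 days of vismodegib, a Smoothened inhibitor, untreated nests positive for the proliferation antigen Ki67, and untreated nests negative for it. Total counts ranged from 6413055 to 10328822 in the vismodegib libraries, from 4929869 to 8359195 in the Ki67-positive libraries and from 4887381 to 7158143 in the Ki67-negative libraries. Group means were 7.96 ± 1.6, 6.8 ± 1.42 and 6.35 ± 0.91 M counts (SD, n = 5 each). All libraries carry the same floxed alleles, and reads over a whole gene model do not separate intact from deleted transcripts, so the levels of the targeted genes check no label. Ptch1 reached 142.35 to 923.01 CPM in the vismodegib libraries and 2052.9 to 3757.62 CPM in the untreated ones. Trp53 reached 80.95 to 136.96 CPM in the vismodegib libraries, 116.7 to 175.41 CPM in Ki67-positive and 116.12 to 153.82 CPM in Ki67-negative libraries.

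The first principal component of log2 CPM held 46.4% of the variance and separated vismodegib libraries (scores −104.5 to −78.8) from untreated libraries (21.6 to 66.5). Ki67-positive and Ki67-negative libraries were interleaved along it. The second component held 11.9% and was set by untreated Ki67-negative library 5 (score 122, against −26.4 to 8.2 for the 14 others), in which 19669 genes had a count, against 21653 to 23322 in the others. Xist, transcribed from the inactive X chromosome, exceeded the Y-linked Ddx3y in vismodegib libraries 1, 2 and 3, Ki67-positive library 5 and Ki67-negative library 5 (6482.4 to 13910.1 CPM, against 17.7 to 60 CPM in the other 10), so the groups differ in their share of such libraries.

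**Figure D1:**
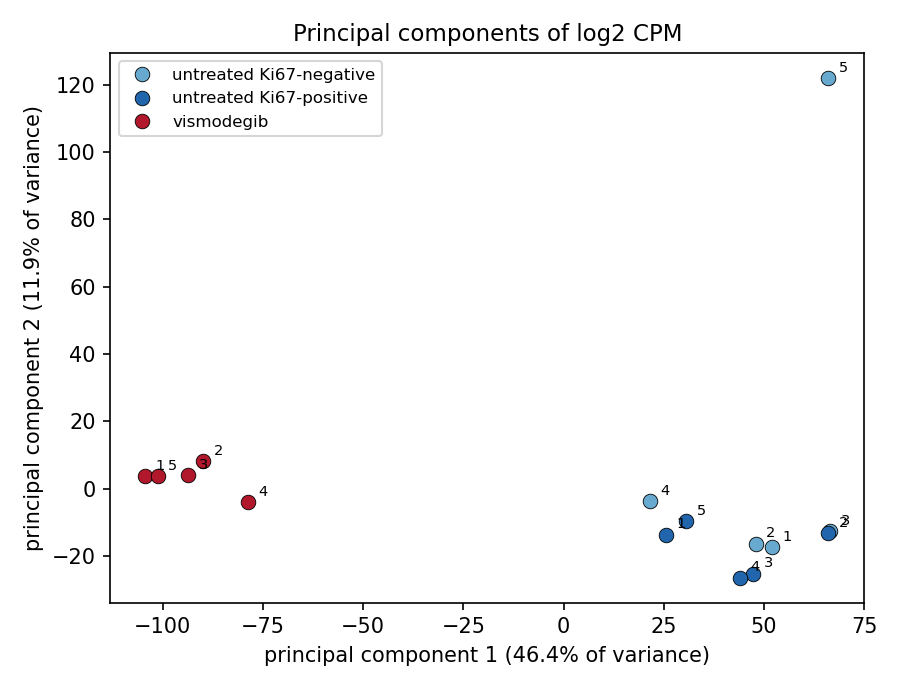
Principal components of log2 CPM, with a point per library coloured by group and numbered within its group; the x axis is component 1 (46.4% of variance) and the y axis component 2 (11.9%). The 5 vismodegib libraries lie at negative scores of component 1, and untreated Ki67-negative library 5 lies at 122 on component 2.

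The comparison of residual nests after vismodegib with untreated Ki67-positive nests asks how treated tumour cells differ from proliferating untreated ones. The vismodegib nests carry no Ki67 label, while the untreated ones were grouped by it. Levels of Mki67 and cell cycle genes in this comparison are thus tied to that choice as well as to treatment. Targets of Hedgehog signalling were lower and genes of differentiating epidermis higher as lists, though neither call holds with an estimated correlation (adjusted p = 0.214 and 0.0739). Hhip, a secreted Hedgehog antagonist that is itself a target gene, fell from 620.7 ± 235.9 to 13.19 ± 9.934 CPM (SD, n = 5 each), a log2 fold change of −5.54 (SE 0.476, edgeR quasi-likelihood adjusted p = 1.09e-06). Krt77, a keratin of suprabasal epidermis, rose from 3.698 ± 2.449 to 741.8 ± 357 CPM (log2 fold change 7.64, SE 0.521, adjusted p = 1.29e-07). Lgr5, a stem cell receptor of the hair follicle, was 519.8 ± 218.5 CPM after vismodegib and 601.1 ± 106.4 CPM in Ki67-positive nests (log2 fold change −0.21, adjusted p = 0.534).

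Of 9 measured Hedgehog targets, 7 fell and 1 rose over all genes tested, and the same numbers held adjusted over the list alone. The list was lower (camera adjusted p = 0.00195, but adjusted p = 0.214 with an estimated correlation). Its mean log2 CPM was 5.1 ± 0.67 after vismodegib and 6.99 ± 0.1 in Ki67-positive nests. Ptch1 fell from 2973 ± 581 to 550.5 ± 382.9 CPM (log2 fold change −2.43, SE 0.468, edgeR adjusted p = 0.00136), and Gli1, the pathway's transcriptional activator, from 339.7 ± 131.1 to 75.56 ± 48.14 CPM (log2 fold change −2.17, SE 0.454, adjusted p = 0.00253). Vismodegib libraries 1 and 5 had the lowest Ptch1 (147.52 and 142.35 CPM) and Gli1 (28.83 and 20.95 CPM). The exception was Ccnd2, which encodes cyclin D2 and rose (log2 fold change 1.73, adjusted p = 0.000121). Of 14 pathway components, 7 fell and 1 rose (camera adjusted p = 0.0405, adjusted p = 0.383 with an estimated correlation). Kif7, a ciliary regulator of Gli proteins, fell (log2 fold change −2.09, adjusted p = 0.00014), the co-receptor gene Cdon rose (1.46, adjusted p = 0.000217), and Smo itself was at −0.35 (adjusted p = 0.127). The call on the components was lost without vismodegib library 1 (adjusted p = 0.0762) or 4 (0.0548), without Ki67-positive library 5 (0.0591), with the stricter filter (0.102) and with the length trend removed (0.0688).

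Epidermal differentiation moved furthest of the 35 lists tested. Of its 29 measured members, 25 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 2.85 (camera adjusted p = 2.05e-20, adjusted p = 0.0739 with an estimated correlation). The median stays the same with Lce1c at the lower limit of its interval. Lor, which encodes the cornified envelope protein loricrin, rose from 1.256 ± 0.9984 to 115.2 ± 46.7 CPM (log2 fold change 6.61, adjusted p = 2.49e-07), and the late cornified envelope gene Lce1a1 by 7.88 (adjusted p = 4.64e-08). Lce1c had 2 counts in the Ki67-positive libraries against 918 after vismodegib, a ratio of 412 (95% counting interval 114 to 3410), and Lce1m, of the same family but outside the list, 2 against 1872, a ratio of 841 (232 to 6950). Il33, an alarmin cytokine of epithelium, rose from 0.2797 ± 0.3831 to 66.63 ± 20.02 CPM, although of the 17 stress and wound keratinocyte genes it belongs to only 3 rose and 1 fell (camera adjusted p = 0.219). Skint9, an immunoglobulin superfamily gene, rose by 6.42 (adjusted p = 3.49e-07).

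Compartments of the hair follicle moved in different directions. Of 16 bulge genes, 8 fell and 3 rose (camera adjusted p = 0.000901, adjusted p = 0.214 with an estimated correlation). Their summed CPM did not fall, with a mean of 6961 after vismodegib and 6948 in Ki67-positive nests. Lhx2, a stem cell transcription factor, fell from 613.2 ± 172 to 70.28 ± 26.08 CPM (log2 fold change −3.12, adjusted p = 1.39e-06), with falls also in Tcf7l1 (−2.74), Tbx1 (−5.21) and the Wnt pathway modulator Dkk3 (−1.78). Of 17 hair germ and matrix genes, 10 fell and 4 rose (adjusted p = 0.0127, adjusted p = 0.214 with an estimated correlation), with falls in Lef1 (−1.93), Pdgfa (−1.90) and Hoxc13 (−4.20). By contrast, 8 of 11 isthmus and infundibulum genes rose and 0 fell (adjusted p = 0.000117, adjusted p = 0.297 with an estimated correlation), among them Sostdc1 (1.78), the glycerol channel gene Aqp3 (3.10), Gata6 (1.52) and Plet1 (1.14). Of 15 sebaceous gland genes, 4 rose, or 6 adjusted over the list alone (camera adjusted p = 0.00854, adjusted p = 0.681 with an estimated correlation), including Dgat2 (2.60) and Mgst1 (2.30), and fry did not call the list (0.0896). The basal layer list was not called (6 of 17 rose and 5 fell, camera adjusted p = 0.27), but Krt14, the basal keratin whose promoter drives Cre, rose from 987.7 ± 258.8 to 2608 ± 333.8 CPM, Ptn rose by 1.56 and the integrin gene Itga6 by 0.70. In the hair shaft list 2 of 7 rose, or 3 adjusted over the list alone (camera adjusted p = 0.0734, and 0.0326 without Ki67-positive library 3), one of them Krt32 (5.22).

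Immediate early and ERK-response genes were lower as a list (9 of 22 fell and 2 rose, camera adjusted p = 0.000887, adjusted p = 0.394 with an estimated correlation). Among those that fell were the ETS factor genes Etv5 (log2 fold change −3.22, SE 0.24) and Etv4 (−4.09), the ERK phosphatase gene Dusp6 (−3.82) and the zinc finger factor gene Egr3 (−2.18). Among 12 Wnt target genes, 3 rose and 2 fell, with Axin2 (2.22, SE 0.241) and Apcdd1 (1.77) higher and Lef1 and Lgr4 (−1.44) lower (camera adjusted p = 0.782). The cell cycle list was not called: 3 of 40 members fell over all genes tested and 0 adjusted over the list alone (camera adjusted p = 0.0523). Mki67 was 683 ± 142 CPM after vismodegib and 775.7 ± 227.9 CPM in Ki67-positive nests (log2 fold change −0.18, edgeR adjusted p = 0.538). Leaving out any of vismodegib library 2 or 3, Ki67-positive library 1, 2 or 3, or Ki67-negative library 1, 2, 3 or 5 gave a lower cell cycle list with an adjusted p between 0.00904 and 0.0485. So did no filter (0.0035), a fit on these groups alone (0.0313), voom (0.00228) and the covariates for Xist (0.0105) and the dendritic score (0.00123), while fry (0.16) and camera with an estimated correlation (adjusted p = 0.797) did not. Trp53 was at −0.42 (adjusted p = 0.0573) and passed without vismodegib library 3 (−0.51), vismodegib library 5 (−0.49) or Ki67-positive library 5 (−0.49). The cyclin-dependent kinase inhibitor gene Cdkn2b fell by a log2 fold change of −2.71 (adjusted p = 1.12e-06), while its list had 3 members up and 3 down of 15 (camera adjusted p = 0.774).

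Markers of other cell types moved with the treatment. Of 12 dendritic and Langerhans cell genes, 10 rose (camera adjusted p = 2.61e-05, adjusted p = 0.214 with an estimated correlation). They included Cd207, which encodes langerin (2.045 ± 2.439 to 34.77 ± 7.347 CPM), and the class II gene H2-Aa (log2 fold change 3.09). The list also holds Epcam and Mfge8, and whether each member marks dendritic cells in these nests was not tested. Of 11 T cell and NK cell genes, 7 rose, or 9 adjusted over the list alone (adjusted p = 0.00195, adjusted p = 0.383 with an estimated correlation), with Cd5 at 1.40 and Cd3e at 2.04. Of 16 myeloid genes, 2 rose, including Csf1r (1.87). The myeloid list was higher at camera adjusted p = 0.016 (adjusted p = 0.681 with an estimated correlation), and not without Ki67-positive library 2 (0.0598) or 3 (0.0635) or by fry (0.0734). Pericyte and smooth muscle genes fell in 5 of 8 cases (adjusted p = 8.32e-05, and adjusted p = 0.0198 with an estimated correlation, the only list to hold). Of these, Mcam fell from 129 ± 28.17 to 12.16 ± 3.429 CPM, Cspg4 by −2.72 and Acta2 by −1.81. The estimated correlation of the pericyte list was −0.037, against 0.699 for fibroblast genes, so the pericyte members did not vary together within groups. The adjusted p of the pericyte list still rose, although its correlation lay below the preset 0.01. A higher adjusted p with an estimated correlation thus need not reflect correlation between genes alone. Cspg4 was 340.7 to 729.5 CPM per Ki67-positive library, where the list summed to a mean of 708.2 CPM. Whether these genes mark pericytes in these nests was not tested. Of 18 fibroblast genes, 8 fell, or 10 adjusted over the list alone (adjusted p = 0.000999, adjusted p = 0.663 with an estimated correlation), including Fbln1 (−1.82) and Col6a1 (−1.65). Of 17 genes of matrix enzymes and invasion, 7 fell, or 8 adjusted over the list alone (adjusted p = 0.00195, adjusted p = 0.383 with an estimated correlation), including Mmp14 (−1.42) and Adamts1 (−1.94), and that list was not called with the fibroblast covariate (0.18). Of 8 melanocyte genes, 5 fell, or 6 adjusted over the list alone (adjusted p = 0.0119, adjusted p = 0.663 with an estimated correlation), including Pmel (−2.11) and Dct (−2.33).

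The widest falls otherwise were in Grm7, a glutamate receptor gene (log2 fold change −7.24), Col14a1, a fibril-associated collagen (382.1 ± 105.6 to 3.557 ± 1.917 CPM), Pkhd1l1 (−6.49) and Cntfr, a cytokine receptor gene (−5.88). Saa3, an acute phase gene, had 3 counts after vismodegib and 509 in Ki67-positive nests, a ratio of 0.0053 (95% counting interval 0.00109 to 0.0156), and was not called by voom (adjusted p = 0.0937) or with the fibroblast covariate (0.0505). In all, 2186 genes were higher and 2311 lower after vismodegib than in Ki67-positive nests (26.0% of 17282, edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05), of which 1247 and 1541 changed over 2-fold, and 3502 genes (20.3%) were separated between the groups, where chance gives 0.79%. Of the lists, 15 were called, 6 higher and 9 lower. The remaining lists were not called: interferon response (4 of 16 rose, adjusted p = 0.0571), class I antigen presentation (5 of 11 rose and 1 fell, 0.0546), Wnt ligands and receptors (7 of 31 rose and 9 fell, 0.774), Notch (2 and 2 of 13, 0.76), BMP and TGF-beta targets (3 and 4 of 12, 0.436), YAP targets (2 and 5 of 12, 0.505), p53 targets (3 and 4 of 13, 0.782), cholesterol synthesis (0 and 3 of 19, 0.815), glycolysis (3 and 2 of 19, 0.728), endothelial cells (0 and 1 of 9, 0.815), mast cells and neutrophils (0 and 1 of 8, 0.549), Schwann cells (1 and 0 of 7, 0.782), skeletal muscle and red blood cells (0 of 2 each, 0.527 and 0.549). The interferon list passed without vismodegib library 2 (0.0463) or 5 (0.0343), Ki67-positive library 2 (0.0373), or Ki67-negative library 1 (0.0482) or 5 (0.0458), with no filter (0.00783) and by voom (0.0111), but not by fry (0.111) and at adjusted p = 0.705 with an estimated correlation. The class I list passed without vismodegib library 2 (0.0267), 4 (0.0383) or 5 (0.046), Ki67-positive library 1 (0.0467) or 2 (0.0372), or Ki67-negative library 4 (0.0265). It also passed with no filter (0.0123), the stricter filter (0.0496), these groups alone (0.0457), the fibroblast covariate (0.0415), voom (0.00815) and fry (0.0292), but had adjusted p = 0.663 with an estimated correlation. The stress and wound list passed with the fibroblast covariate (0.0415), and the hair shaft (0.00277) and YAP lists (0.0292) by fry. Median, mean and test differed in sign for the Wnt target, Wnt ligand, YAP, cyclin-dependent kinase inhibitor and cholesterol lists.

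The dendritic and Langerhans cell score, the mean log2 CPM of that list, was 5.44 to 6.41 in every vismodegib library and 2.80 to 4.43 in Ki67-positive ones, with no overlap. The score is thus tied to the treatment, and as a covariate it takes up part of the treatment difference. A call lost with it may reflect that tie, so the losses below do not show that a result depends on dendritic cells. With the score as a covariate, 145 genes were higher and 322 lower, and 6 of the 29 epidermal differentiation genes rose (median 1.05). That covariate ended the calls on Hedgehog targets (adjusted p = 0.119), Hedgehog components (0.64), hair germ and matrix (0.373), isthmus and infundibulum (0.119), sebaceous gland (0.478), T cell and NK cell (0.401) and melanocyte genes (0.508). The dendritic list itself was not called either (0.799). This follows by construction, since the score is the mean of that list, whose members include Cd207 and H2-Aa. The epidermal, bulge, immediate early, matrix enzyme, pericyte, fibroblast (4.14e-17) and, in the other direction, myeloid lists (9.77e-05) were called, and the mast cell and neutrophil (8.51e-16), endothelial (0.00149) and glycolysis lists (0.0333) became called, all lower. Hhip, Krt77, Lor, Lce1a1, Il33, Skint9, Lhx2, Tcf7l1, Tbx1, Dkk3, Sostdc1, Axin2, Etv4, Etv5, Dusp6, Cdkn2b, Mcam, Cspg4 and Col14a1 stayed below an adjusted p of 0.05, while Ptch1 (log2 fold change −1.18), Gli1 (−1.15), Ccnd2 (1.39), Kif7 (−1.02), Krt14 (0.75), Aqp3 (0.76) and Lef1 (−0.99) did not. Nor did Pdgfa, Hoxc13, Krt32, Plet1, Gata6, Ptn, Itga6, Dgat2, Mgst1, Lgr4, Apcdd1, Egr3, Adamts1, Fbln1, Cd5, Cd3e, Csf1r, H2-Aa, Cd207, Pmel and Dct. Nests may share animals, in which case all these p-values are too small.

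**Figure D2:**
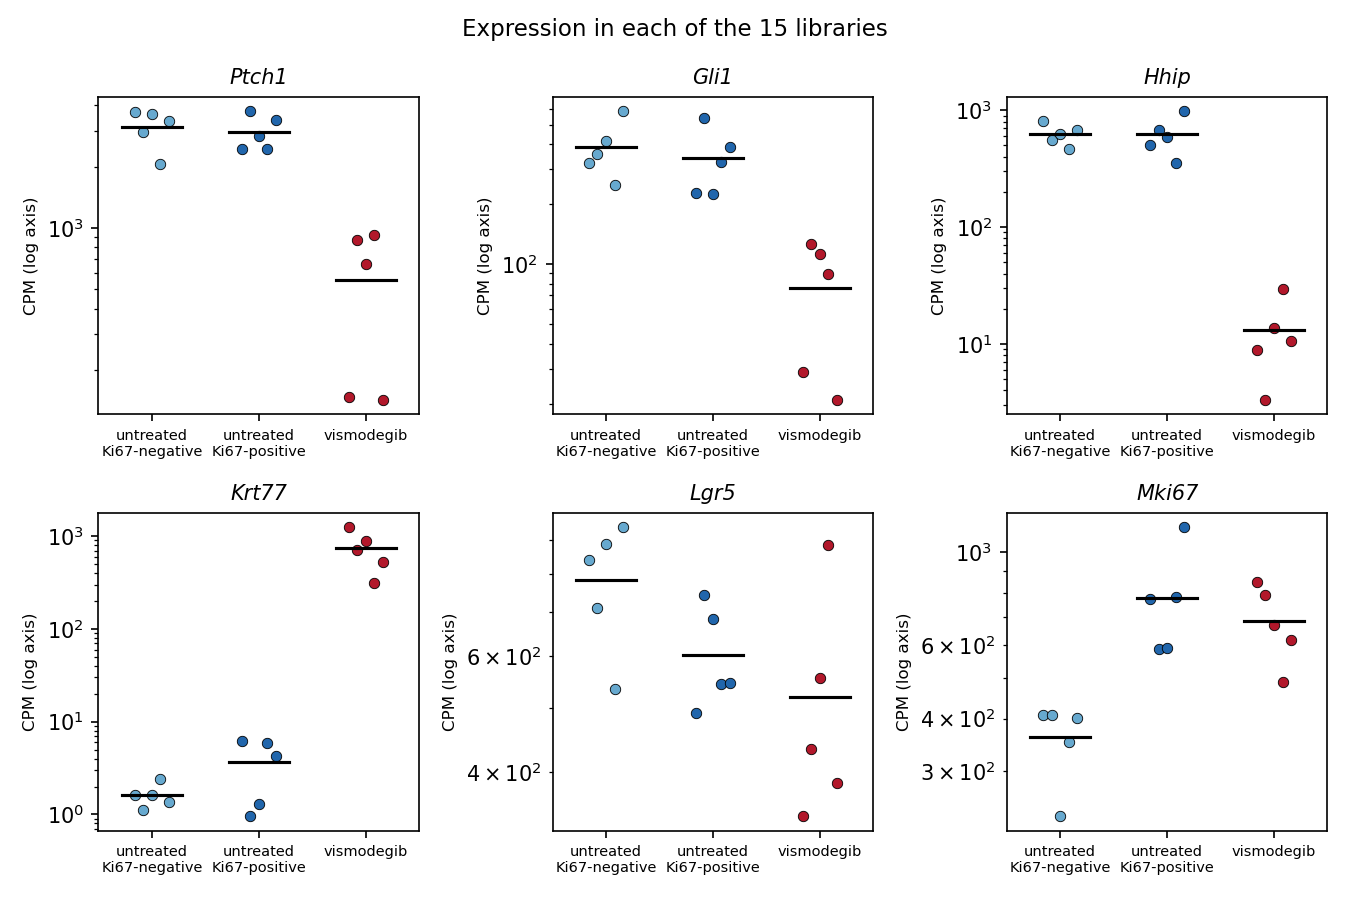
Expression of Ptch1, Gli1, Hhip, Krt77, Lgr5 and Mki67 in CPM on a log axis, with a point per library and a line at the group mean for untreated Ki67-negative, untreated Ki67-positive and vismodegib nests (n = 5 each). Ptch1, Gli1 and Hhip lie lower and Krt77 higher in every vismodegib library than in every untreated one, while Lgr5 overlaps between the groups and Mki67 is lower in Ki67-negative libraries.

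Against untreated Ki67-negative nests, the comparison asks how residual nests differ from untreated nests without the Ki67 label. Hedgehog targets and bulge genes were again lower and epidermal differentiation genes higher, and cell cycle genes were higher too. None of these list calls holds with an estimated correlation (adjusted p = 0.27 for Hedgehog targets, 0.143 for bulge, 0.083 for epidermal differentiation and 0.554 for cell cycle). Hhip fell from 627.6 ± 131.9 to 13.19 ± 9.934 CPM (log2 fold change −5.56, SE 0.477, edgeR quasi-likelihood adjusted p = 9.74e-07, n = 5 each). Krt77 rose from 1.625 ± 0.4861 to 741.8 ± 357 CPM (log2 fold change 8.82, adjusted p = 4.96e-08). Mki67 rose from 360.8 ± 74.49 to 683 ± 142 CPM (log2 fold change 0.92, SE 0.199, adjusted p = 0.00189). The untreated nests are named for lacking Ki67, the protein of Mki67, so part of any difference in it and in genes transcribed with it is built into the groups.

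The cell cycle list was higher after vismodegib: 21 of 40 members rose, or 23 adjusted over the list alone, and 0 fell (camera adjusted p = 7.17e-05, adjusted p = 0.554 with an estimated correlation). Apart from Mki67 they included Ccna2, which encodes cyclin A2 (log2 fold change 1.03, edgeR adjusted p = 0.00173), and the mitotic spindle genes Nusap1 (1.19, adjusted p = 0.00242) and Hmmr (0.93, adjusted p = 0.00269). The mean log2 CPM of the list was 4.8 ± 0.28 after vismodegib, 4.14 ± 0.37 in Ki67-negative and 5.16 ± 0.32 in Ki67-positive nests. The labels give no Ki67 status for the vismodegib nests, so their place between the untreated groups cannot be read as an effect of treatment alone. Of 15 cyclin-dependent kinase inhibitor and quiescence genes, 5 rose and 3 fell (camera adjusted p = 0.948), with Cdkn2b at −2.88.

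Of 9 Hedgehog targets, 5 fell, or 6 adjusted over the list alone, and 1 rose (camera adjusted p = 0.00689, adjusted p = 0.27 with an estimated correlation). Ptch1 fell from 3147 ± 682.1 to 550.5 ± 382.9 CPM (edgeR adjusted p = 0.000977) and Gli1 by −2.35 (adjusted p = 0.00133), while Ccnd2 rose by 2.07. Of 14 pathway components, 7 fell, or 8 adjusted over the list alone, and 1 rose (camera adjusted p = 0.0187, adjusted p = 0.278 with an estimated correlation, and 0.0519 with the stricter filter). Boc, a Hedgehog co-receptor gene, was at −0.98 (adjusted p = 0.000125), Kif7 at −1.71 and Cdon at 1.23. Smo was at −0.41 (adjusted p = 0.0654) and passed without vismodegib library 2 (−0.47) or 3 (−0.49), without Ki67-negative library 4 (−0.51) or with the covariate for Xist (−0.51). Lgr5 was 782.2 ± 163 CPM in Ki67-negative nests (log2 fold change −0.59, adjusted p = 0.0527) and passed with DESeq2 (−0.58) and voom (−0.74), and without vismodegib library 4 (−0.87) or Ki67-negative library 4 (−0.70). Trp53 was at −0.23 (adjusted p = 0.271).

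Epidermal differentiation genes rose in 26 of 29 cases, over all genes and adjusted over the list alone (median log2 fold change 3.38, camera adjusted p = 9.46e-20, adjusted p = 0.083 with an estimated correlation). The median stays the same with Lce1c at the lower limit of its interval. Lor rose by 6.74 and Lce1a1 by 7.75. From 2 counts in Ki67-negative nests, Lce1c had a ratio of 373 (95% counting interval 103 to 3090) and Sprr4, a small proline-rich cornified envelope gene outside the list, of 2500 (692 to 20600), though Sprr4 was not called by voom (adjusted p = 0.118). Il33 rose by 6.43 and Skint9 by 7.63. Of 11 isthmus and infundibulum genes, 8 rose (camera adjusted p = 4.41e-05, adjusted p = 0.27 with an estimated correlation), including Sostdc1 (2.71), Aqp3 (4.31) and Gata6 (1.65). Of 16 bulge genes, 9 fell, or 10 adjusted over the list alone, and 2 rose (adjusted p = 0.000251, adjusted p = 0.143 with an estimated correlation). Those that fell included Lhx2 (−3.24), Dkk3 (−2.03), Tcf7l1 (−2.30) and Tbx1 (−4.52). The summed CPM of the bulge list had a mean of 6961 after vismodegib and 7644 in Ki67-negative nests. Of 17 hair germ and matrix genes, 8 fell, or 9 adjusted over the list alone, and 4 rose (adjusted p = 0.0209, adjusted p = 0.27 with an estimated correlation), including Lef1 (−2.34), Pdgfa (−2.06) and Hoxc13 (−4.01). Of 7 hair shaft genes, 4 rose, Krt32 by 6.44 (adjusted p = 0.0382, adjusted p = 0.27 with an estimated correlation). That list was not called without vismodegib library 3 (0.0966) or Ki67-negative library 1 (0.0572), with the stricter filter (0.734), the fibroblast (0.0637) or Xist (0.0544) covariate, or voom (0.105). Of 15 sebaceous genes, 4 rose, including Dgat2 at 2.46 (adjusted p = 0.00904, adjusted p = 0.699 with an estimated correlation, and 0.0709 by fry). In the basal layer list, Krt14 (1.73), Krt5 (1.01), Ptn (2.53) and Itga6 (0.78) rose, while the list had 7 of 17 members up and 5 down (camera adjusted p = 0.413).

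Immediate early and ERK-response genes were lower (12 of 22 fell and 2 rose, camera adjusted p = 0.000721, adjusted p = 0.428 with an estimated correlation), with Etv5 at −3.35, Etv4 at −4.33 and Dusp6 at −3.94. In the Wnt target list 3 of 12 rose and 3 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.971), with Axin2 at 2.10 and Apcdd1 at 1.98. Dendritic and Langerhans cell genes rose in 7 of 12 cases (adjusted p = 0.000261, adjusted p = 0.278 with an estimated correlation), with Cd207 at 3.69 and H2-Aa at 2.67, and T cell and NK cell genes in 5 of 11, or 6 adjusted over the list alone (adjusted p = 0.00757, adjusted p = 0.437 with an estimated correlation), with Cd5 at 2.15. Of 8 pericyte and smooth muscle genes, 5 fell (adjusted p = 7.17e-05, and adjusted p = 0.0208 with an estimated correlation, the only list to hold), with Mcam at −3.13 and Cspg4 at −3.05. The estimated correlation of that list was −0.025 here. Fibroblast genes fell in 8 of 18 cases, or 9 adjusted over the list alone (adjusted p = 0.000321, adjusted p = 0.554 with an estimated correlation), Fbln1 by −2.07. Matrix enzyme genes fell in 9 of 17, or 10 adjusted over the list alone (adjusted p = 0.000251, adjusted p = 0.27 with an estimated correlation), Mmp14 by −1.68, and with the fibroblast covariate that list was not called (0.0637). Melanocyte genes were not called as a list (3 of 8 fell and 1 rose, adjusted p = 0.185, and 0.0213 without Ki67-negative library 4), with Pmel at −1.64. Myeloid genes were not called either (2 of 16 rose and 1 fell, adjusted p = 0.509), although Csf1r rose by 1.76, and the list was called higher with the fibroblast covariate (0.00186).

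In all, 2658 genes were higher and 2855 lower (31.9% of 17282, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 1395 and 1825 of them over 2-fold, and 3550 genes (20.5%, against 0.79% by chance) were separated. Of the lists, 15 were called, 7 higher and 8 lower. Class I antigen presentation was not called (5 of 11 rose and 1 fell, adjusted p = 0.0954, but 0.0482 without vismodegib library 2 and 0.0144 without Ki67-negative library 4, 0.0256 with no filter, 0.0118 by voom and 0.0228 by fry, and adjusted p = 0.624 with an estimated correlation), though H2-K1 (0.99) and B2m (0.94) rose. The other lists had adjusted p-values of 0.185 to 0.971, though YAP targets passed by fry (0.00748) and the red blood cell list by fry (0.00159) and with no filter (0.018), and median, mean and test differed in sign for the stress and wound, Wnt target, Wnt ligand, Notch, YAP and interferon lists. The dendritic and Langerhans cell score was 3.24 to 4.74 in Ki67-negative libraries, below every vismodegib library. It is thus tied to the treatment here too, and a call lost with it as a covariate may reflect that tie. With it as a covariate 359 genes were higher and 650 lower, and 7 of the 29 epidermal differentiation genes rose (median 1.81). That covariate ended the calls on Hedgehog targets (adjusted p = 0.128), Hedgehog components (0.324), hair germ and matrix (0.335), hair shaft (0.0801), sebaceous gland (0.36), dendritic (0.939) and T cell and NK cell genes (0.649), and the mast cell and neutrophil (3.13e-16), endothelial (0.0174) and myeloid lists (7.38e-07) became called, all lower. Under it Hhip, Krt77, Lor, Lce1a1, Lhx2, Tcf7l1, Lef1, Krt14, Sostdc1, Etv5 and Mcam stayed below an adjusted p of 0.05, and Ptch1 (−1.39), Gli1 (−1.47), Kif7 (−0.79), Mki67 (0.28), Ccna2 (0.91), Nusap1 (0.90), Hmmr (0.52) and Aqp3 (2.30) did not. Nor did Boc, Hoxc13, Gata6, Krt5, Itga6, Dgat2, Apcdd1, H2-K1, B2m, Sprr4, Cd5, Csf1r, H2-Aa, Cd207 and Pmel. The loss of the dendritic list follows by construction, and its members H2-Aa and Cd207 are part of the score. Nests may share animals here too, which would make the p-values too small, and any batch of the Ki67-negative libraries, which have later accession numbers, cannot be separated from the group in these 5513 genes.

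**Figure D3:**
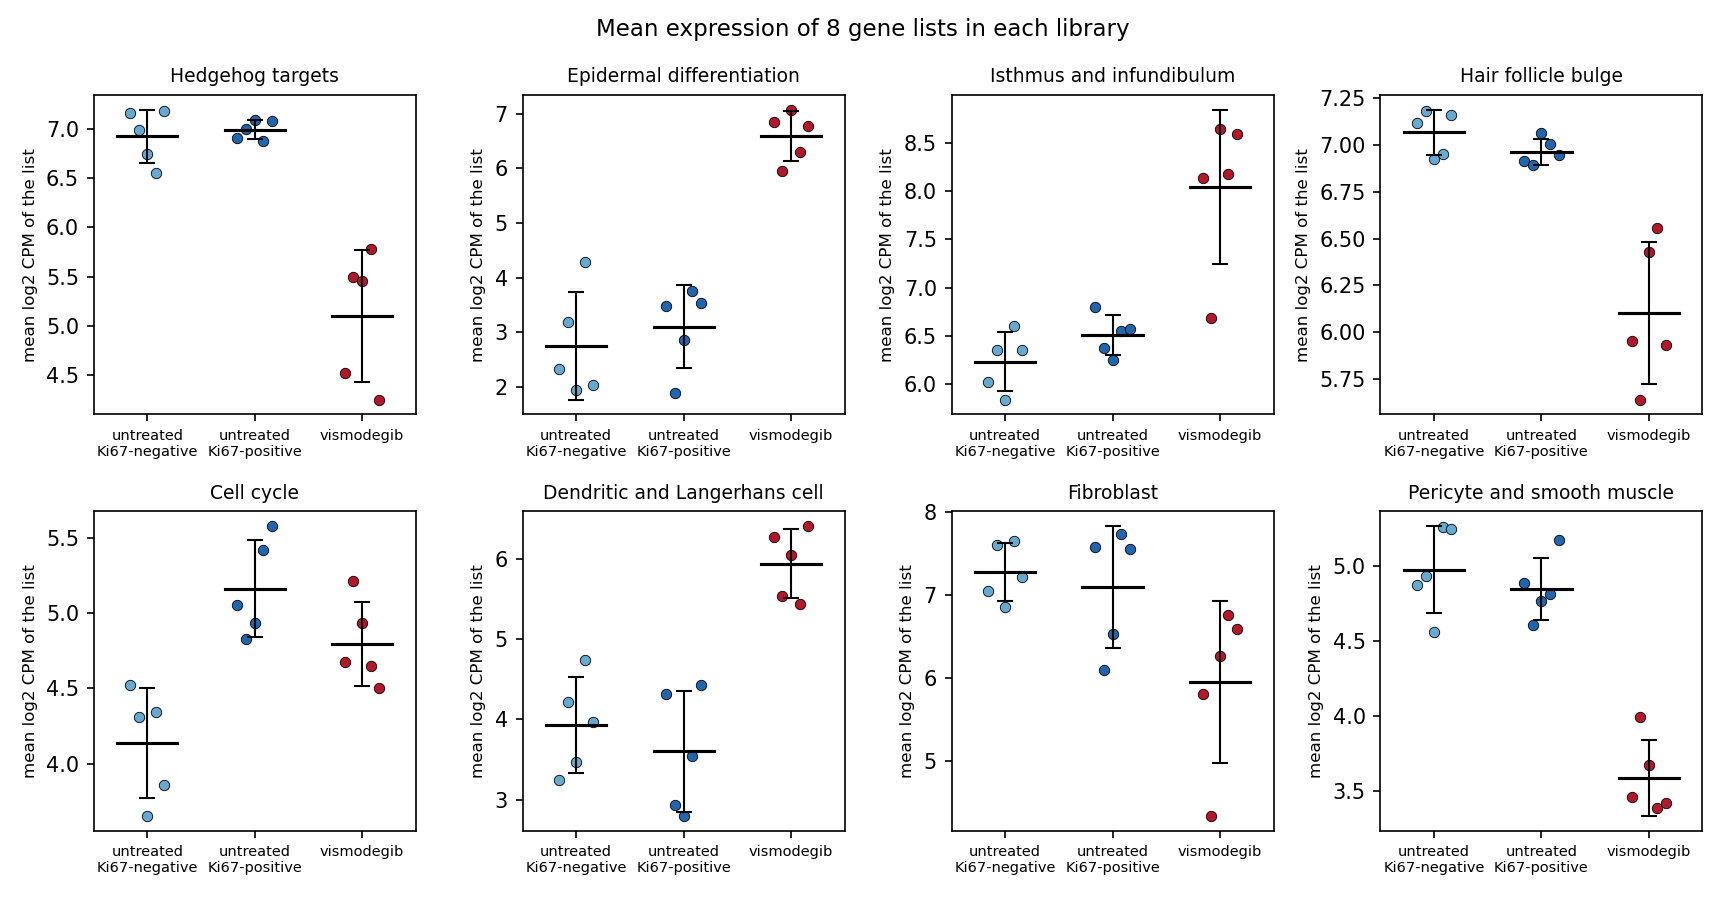
Mean log2 CPM of the genes of 8 lists in each library, with a point per library, a line at the group mean and bars of 1 SD (n = 5 per group). Hedgehog target, bulge and pericyte lists lie lower and the epidermal differentiation and dendritic and Langerhans cell lists higher after vismodegib than in either untreated group, and the cell cycle list is lowest in Ki67-negative nests.

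The responses against both untreated groups shared most of their genes. Of those called, 1804 were higher and 1970 lower in both comparisons, 3774 in all, and 4 were called in opposite directions. Independent lists would share 336 and 382. Log2 fold changes correlated across genes with r = 0.924 (covariance 1.31), where genes are not independent replicates. The comparisons share the 5 vismodegib libraries: in 20 simulations with no change, 0 genes were shared in each, r was 0.498 (0.476 to 0.516) and the covariance 0.075. With no gene changed almost none is called, so this count of 0 does not measure what shared libraries add when many genes change. With the vismodegib libraries split so that each untreated group had its own, a median of 2104 genes (1909 to 2191 over 20 splits) changed the same way, against 151 and 141 for independent lists, with r = 0.765 and a covariance of 1.45. Hhip, Ptch1, Gli1, Lhx2 and Dusp6 were lower and Krt77, Lor, Il33, Sostdc1 and Axin2 higher in both. With the dendritic and Langerhans cell score, which is tied to the treatment, as a covariate, 455 genes were shared.

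Untreated Ki67-negative nests differed from Ki67-positive ones in 30 genes, all lower, of which 10 belong to the cell cycle list and the others to none of the lists. Of 40 cell cycle genes, 10 fell over all genes tested and 32 adjusted over the list alone, and 0 rose (median log2 fold change −1.10, camera adjusted p = 1.07e-63, and adjusted p = 0.0191 with an estimated correlation). Kif11, a mitotic kinesin gene, fell from 101.3 ± 25.72 to 33.27 ± 13.89 CPM (log2 fold change −1.60, SE 0.258, edgeR quasi-likelihood adjusted p = 0.0211, n = 5 each). Other members that fell were the kinetochore gene Cenpe (−1.47), the checkpoint gene Bub1b (−1.39) and Hmmr (−1.25), and outside the list the kinetochore gene Nuf2 (−1.84, adjusted p = 0.0211), the mitotic kinesin gene Kif23 (−1.71) and the DNA glycosylase gene Neil3 (−1.87, adjusted p = 0.0384). Mki67 was at −1.10 (adjusted p = 0.0291), but Ki67 named these groups, so its difference is no finding, and genes transcribed with it are tied to the same choice. Hedgehog targets were alike in level (0 of 9 called, median log2 fold change 0.02, camera adjusted p = 0.824), with Ptch1 at 0.08 (edgeR adjusted p = 0.984), Gli1 at 0.18 (0.964), Smo at 0.06 (0.969), Lgr5 at 0.38 (0.819) and Trp53 at −0.19 (0.869).

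In this comparison 0 genes were higher and 30 lower in Ki67-negative nests (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 29 of them over 2-fold. At an unadjusted p under 0.05, 582 were higher and 572 lower, DESeq2 called 5 higher and 83 lower, and voom called 0 higher and 12 lower. Separated genes numbered 203 (1.2%, against 0.79% by chance). The 30 calls depended on which libraries were included, and not on any single one. Genes lower numbered 0 without Ki67-positive library 4 or without Ki67-negative library 3, 4 or 5, and 2 without Ki67-positive library 5. They numbered 12 without Ki67-negative library 2 and 43 without Ki67-negative library 1, and 1 gene was higher without Ki67-positive library 2. In a fit on these 10 libraries alone, 0 were lower. Every gene named above as lower lost its call without Ki67-positive library 5, all but Kif11 and Nuf2 did without Ki67-negative library 2, and voom did not call Nuf2, Bub1b, Kif23 or Neil3. Neil3 also lost its call without Ki67-positive library 2 or vismodegib library 1, 3, 4 or 5. The cell cycle list was called in each of 26 settings, with adjusted p-values from 3.38e-74 to 0.0191. The calls on myeloid (adjusted p = 0.000333) and interferon response genes (0.014), higher in Ki67-negative nests, and on melanocyte genes (0.0318), lower, each had 0 members called and an adjusted p = 0.926 with an estimated correlation. The myeloid call was lost without Ki67-positive library 2 (0.105), the interferon call without Ki67-negative library 5 (0.857), and the melanocyte call without Ki67-positive library 2 (0.171), 3 (0.0902) or 4 (0.153) or Ki67-negative library 1 (0.0551) or 4 (0.425). No member of the other 31 lists was called, and their adjusted p-values were 0.124 or more. The number of lists called was 7 without Ki67-positive library 1. Some passed with 1 library left out: epidermal differentiation without Ki67-positive library 2 (0.0135) or Ki67-negative library 4 (8.28e-05), isthmus and infundibulum without Ki67-positive library 3 (0.0448), sebaceous gland without Ki67-negative library 1 (0.0479), and matrix enzymes without Ki67-positive library 1 (0.00313) or Ki67-negative library 3 (0.0248). The dendritic list did so without Ki67-positive library 1 (0.0367) or 5 (0.03), and the mast cell and neutrophil list without Ki67-positive library 1 (0.000697) or 5 (0.0489) or Ki67-negative library 3 (0.0187). With the dendritic and fibroblast covariates the isthmus list passed (0.0134 and 0.0152), and with the dendritic covariate the epidermal list (0.000166), all lower. With no filter the matrix enzyme and mast cell lists (0.0466 each) and the red blood cell list (0.0215) passed. The calls on interferon and myeloid genes were lost by fry (0.91 each). That on interferon genes was also lost by voom (0.609), the stricter filter (0.0801) and these groups alone (0.0663), and that on melanocyte genes by voom (0.0763), fry (0.91) and the dendritic covariate (0.308). Median, mean and test differed in sign for the Hedgehog target, basal layer, cyclin-dependent kinase inhibitor, sebaceous, YAP and Schwann cell lists. Nests of either group may share animals, which would make these p-values too small, and the 30 genes cannot be separated from any batch of the Ki67-negative libraries, which have later accession numbers.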

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

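Vismodegib library 2 had the lowest mean log2 CPM of its group for the myeloid list (2.785, others 4.255 to 4.576), the isthmus and infundibulum list (6.683, others 8.132 to 8.646) and the p53 target list (5.627, others 5.759 to 5.812). Each value here and below lies far from the others of its group of 5 by Dixon's test. Of 339 groups tested, 19 held such a library, against 16.9 given by chance alone (about 1 in 20), so their number is close to what chance gives. Vismodegib library 3 was highest for the hair shaft list (3.977, others 2.603 to 2.967) and vismodegib library 1 for the skeletal muscle list (4.87, others 1.422 to 2.239). Vismodegib library 4 had the most Col14a1 (6.93 CPM, others 2.21 to 3.14) and vismodegib library 1 the only Saa3 (0.46 CPM, others 0).

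Ki67-positive library 5 had the highest level in its group of the cornified envelope gene Lor (3.03 CPM, others 0.71 to 0.96), of Ptn (181.4 CPM, others 83.16 to 100.8) and of the Langerhans cell gene Cd207 (6.27 CPM, others 0.12 to 1.84). Ki67-positive library 2 was highest for the pericyte gene Cspg4 (729.5 CPM, others 340.7 to 385.1) and held the only Lce1m (0.32 CPM, others 0). Ki67-negative library 1 was highest for the sebaceous gland list (5.333, others 2.276 to 2.977) and its member Mgst1 (50.82 CPM, others 13.16 to 17.85). Ki67-negative library 4 was highest for Itga6 (421.7 CPM, others 289.6 to 305.7) and Saa3 (96.48 CPM, others 2.02 to 21.39). Ki67-negative library 5 was highest for Cspg4 (796.8 CPM, others 470.0 to 507.8) and the interferon response list (4.152, others 1.524 to 2.252), and had the fewest genes with a count (19669, others 21842 to 22325).

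All tests weighed below were chosen after the results were seen. The rise of epidermal differentiation genes against Ki67-positive nests was set against the biological reading, a change of the tumour cells under vismodegib. Gene length bias is refused, since 25 members still rose with the length trend removed. For a lower share of tumour cells with more surrounding stroma, pericyte, fibroblast and endothelial genes gave no sign of a rise, but they do not settle it. Whether the pericyte genes mark pericytes here was not tested, and the fibroblast means overlapped between the groups. The mean log2 CPM differed by −1.26 (SE 0.15) for pericyte and smooth muscle genes, −1.15 (SE 0.55) for fibroblast and −0.02 for endothelial genes. More epidermis or immune cells are not refused, since the dendritic (2.34) and T cell and NK cell lists (1.54) were higher. Adjacent epidermis captured with the nests, which would bring Langerhans cells, cannot be told apart from a treatment effect: 6 members rose with the dendritic cell score as a covariate, the median going from 2.85 to 1.05 and its typical SE from 0.7 to 1.06. The score is above every untreated library in all 5 vismodegib libraries, so the fall to 6 may reflect either shared epidermis or the tie between score and treatment.

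For the fall of Hedgehog targets, the biological explanation is inhibition of Smoothened and the technical one is tumour RNA diluted by other RNA. Dilution would lower every tumour gene by the same factor. The lower 95% limit of the log2 fold change of Lgr5 was −0.7, while the upper limit of Hhip was −4.5. Dilution of Lgr5-expressing cells thus cannot account for the fall of Hhip if vismodegib left Lgr5 per tumour cell unchanged. That condition was not tested, and a rise of Lgr5 per cell could hide dilution. The limits were taken against Ki67-positive nests only. Limits were not compared for Ptch1, Gli1 or the other targets, and Ptch1 and Gli1 fell less than Hhip. Vismodegib libraries 1 and 5 had the lowest mean log2 CPM of Hedgehog targets (4.518 and 4.246). They also had the highest dendritic scores of their group (6.27 and 6.412). For targets other than Hhip, dilution is left open whether or not Lgr5 per cell changed. Replacement of tumour cells by other cells with Lgr5 was not tested.

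Ki67-negative library 5 stood apart on the second principal component, and no biological explanation was tested. Low depth is refused, since it had 7.16 M counts, the most of its group. A Ki67-positive nest under the wrong label is refused as well, since its Mki67 was 402 CPM, within the 234 to 408 CPM of its group and below the 586.7 CPM of the lowest Ki67-positive library. Few starting RNA molecules fit: its spread at log2 CPM 2 to 4 was 1.8 times that of the highest other untreated library, against 1.06 times at high abundance. Few molecules may thus lie behind its missing genes, of which 68 were at 0 while expressed in the other untreated libraries, against 0 to 3 in those.

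Regrouping the libraries of a comparison gave as many higher genes as the labels in 1 of 100 splits for vismodegib against Ki67-positive nests (the labelled split itself) and as many lower genes in 1. A regrouping has no direction, so the larger of its higher and lower counts was taken, which was at most 2 in the other splits. Against Ki67-negative nests it was 1 and 1 (at most 438 in the others, taken the same way), for lower genes between the untreated groups 1 (at most 19), and for genes changed the same way against both 1 (at most 0). As many gene lists were called in 17, 9 and 86 of 100 splits in the same order of comparisons, so chance is not excluded for the numbers of lists. Other splits with vismodegib libraries mix treated and untreated ones unevenly, so their lists may carry part of the treatment difference. The mixing also widens the spread within groups, which lowers counts of genes, shared ones included. These splits are thus no clean measure of chance. Other splits of the untreated libraries called up to 15 lists, against 4 with the labels.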

How the results depend on the processing

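Choices added after the data were seen are the Xist covariate, the dendritic score covariate and the removal of the length trend. Of 335 results on named genes, 249 kept their side of the threshold in all settings of the first set and 129 in all settings, and of 105 on lists 56 and 51. No paired analysis was possible because the labels tie no library to an animal. Alternatives meant for files without counts were not run, since the files hold counts. Depth limits the genes with few counts, whose ratios have intervals of counting error. The median log2 fold change moved by 0.03 or less.

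With the dendritic score as a covariate, vismodegib against Ki67-positive nests had 145 genes higher and 322 lower, against Ki67-negative nests 359 and 650, and 455 were shared. Every vismodegib library scored above every untreated one, so these lower counts may reflect the tie between score and treatment. The cause was not tested. Lists that reversed under it (adjusted p) were glycolysis (0.0333), T cell and NK cell (0.401), myeloid cell (9.77e-05) and melanocyte genes (0.508) against Ki67-positive, and T cell and NK cell (0.649) and myeloid cell genes (7.38e-07) against Ki67-negative nests. Genes that reversed (log2 fold change) were Jag1 (0.12), Fjx1 (0.16), Tapbp (−0.087), Slc2a1 (−0.072), Klrk1 (−0.39), Cd3e (−0.83), Ptprc (−0.24) and Laptm5 (−1.79) against Ki67-positive, and Cd3g (−1.18), Cd3e (−0.44), Ptprc (−0.80) and H2-Aa (−0.076) against Ki67-negative nests. H2-Aa is itself part of the score. With the fibroblast covariate the fibroblast list reversed by construction (adjusted p = 0.98 and 0.855), and Gata3 (−0.053) against Ki67-negative nests for a cause that was not tested.

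Between the untreated groups, 5 genes were higher and 83 lower by DESeq2, 12 lower by voom and 0 lower with only these groups fitted, which leaves fewer libraries. Lists called there numbered 7 with no filter, 2 by voom, 1 by fry and 1 with an estimated correlation, which also left 1 in each comparison with vismodegib. The cause was not tested. Leaving out 1 library at a time gave 1831 to 2624 higher and 1935 to 2595 lower genes against Ki67-positive nests, 2193 to 2826 and 2373 to 2945 against Ki67-negative nests, 0 to 1 and 0 to 43 between the untreated groups, and 3184 to 4140 shared. Lists called were 14 to 18, 14 to 17 and 3 to 7. Without Ki67-negative library 5 the shared genes were 4140.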

Other observations

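Ribosomal protein genes were looked at after the results were seen. Of 92 measured, 49 rose and 1 fell after vismodegib against Ki67-positive nests (median log2 fold change 0.78, quartiles 0.27 and 1.08, edgeR quasi-likelihood), 53 rose and 1 fell against Ki67-negative nests (median 0.84), and 0 changed between the untreated groups (median −0.08). With the length trend removed, 44 and 42 rose (medians 0.62 and 0.61). They took 0.83% to 1.2% of the counts in vismodegib libraries and 0.38% to 0.6% in untreated ones. Their transcripts are short, and log2 fold changes ran against gene length with Spearman correlations of −0.123 and −0.153 in the comparisons with vismodegib.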
